A study of Oryza sativa with 18 samples.

How the data were processed

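The series measured total RNA from embryos of germinating rice seeds of a wild type line and the csa mutant at 3 h, 6 h and 12 h of imbibition, in 3 samples per genotype and time. Per the labels, each extraction pooled 5 seeds and libraries were run on an Illumina instrument. The 3 deposited tables hold one comparison each, csa against wild type at 1 time, and list only called genes. Per the file headers, each holds a raw read count for every replicate, a log2 fold change, a p-value and a false discovery rate (FDR) from the authors, and annotation text. DESeq2 is named, without a version, in the submitters' processing notes. The read aligner, the counting tool, the treatment of strand and of reads shared between gene copies, and the genome build are not given in the sources used here.

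The count columns hold whole numbers as the authors deposited them, and no normalized values. The deposited log2 fold changes are csa over wild type, with absolute values of 1 or more in every entry, and the deposited p-values and FDR values reach an FDR of 0.05, which matches the thresholds given with the tables. Every sample column was matched to a sample by its name, leaving 0 columns unmatched, and no pair of libraries held identical values. The third wild type sample at 12 h carries a genotype field that names the mutant against its title and description. Samples were grouped by title, which put it with the wild type.

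Genes that were not called, and the library totals, are not part of the tables used here. The main results are therefore the authors' own calls, counted by direction. Library scaling was recovered from the tables by finding the factors for which the ratio of mean scaled counts gave the deposited log2 fold changes. The residual SD was 0.00119, 0.00400 and 0.00324 log2 units at 3 h, 6 h and 12 h. Without scaling the median log2 fold change of the listed genes would shift by 0.07, 0.05 and 0.04, and 0 genes would change sign. The number of genes tested was recovered from the ranks implied by the deposited p and FDR values, as 21397 at 3 h, 23117 at 6 h and between 21239 and 21245 at 12 h. By the same ranks 3000, 5394 and 112 genes passed the FDR threshold at any fold change. Depth per library is unknown, and precision is given by the spread between replicates.

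Values per gene are means of scaled counts with SD, and log2 fold changes with a standard error from the spread of the replicates. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Intervals on shares of called genes and on medians over genes treat genes as the units. Neither they nor the floors cover the spread between replicates. Values of genes taken at different times come from tables scaled separately, and only differences in which such scaling cancels were tested between times.

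Direction was tested for 25 lists of genes, defined by search terms on the annotation text. For each list with 5 or more called members, Fisher's exact test (two-sided) compared its higher and lower calls with all other calls of that time, with Benjamini-Hochberg adjustment over the lists of that time. Only direction within the calls can be tested this way, and genes are not independent replicates. The storage and oil body list takes in lipid transfer proteins by its search terms. The search terms also caught unrelated annotations, such as immunoglobulin-like domains in the storage list at 6 h. Others were an amylase inhibitor in the starch and sucrose list and F-box genes in the cell cycle list. Uncalled members of the panel and lists are not in the tables used here, so no count adjusted over the list alone can be given. Annotation text was missing for 95, 193 and 5 entries at 3 h, 6 h and 12 h.

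Genes named in the text follow a rule that, like the panel, the lists and most other settings tried, was fixed before the data were examined: per time, the 6 called genes with the smallest FDR in each direction whose replicates do not overlap between genotypes and which carry a descriptive annotation, up to 3 members of each list with 5 or more called members (4 for lists that passed), the 31 panel genes where called, and up to 10 genes called at all 3 times. Non-overlap of 3 against 3 values arises by chance in 10% of genes. Genes named as examples of opposite directions were chosen after their values were seen. RefSeq annotation (assembly ASM3414082v1) was used only for names and gene order. The gene numbers in the tables matched RefSeq for 77.0%, 77.7% and 84.7% of entries.

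The listed genes were refitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, recovered scaling factors as library sizes). A gene was kept when its p was no larger than the largest p of the authors' list (0.00694, 0.0117 and 0.000255), its absolute log2 fold change was at least 1 and its direction was the same. This refit served for leaving out each library in turn, for the replicate number as a block, for other splits of the libraries and for an interaction term between times. A z test for differences between times was planned only if the tables held standard errors, and otherwise the values were to stand side by side untested. The tables hold none, and the edgeR interaction was added after they had been seen, as a departure from that plan. Because dispersion was estimated from called genes alone, these refits describe how the calls depend on the libraries and are not a test of all genes.

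The refit was tested on simulated counts drawn around the observed means of the same 1050, 2388 and 85 genes with known changes and a dispersion of 0.04. By p and direction it recovered 79% of genes changed by a log2 fold of 1 at 3 h, 87% at 6 h and 30% at 12 h, and 100% of those changed by a log2 fold of 2 at each time. The fold threshold of the refit was not applied to the simulated genes, and applying it could only lower these shares. These shares rest on 100 changed genes of each size at 3 h and 6 h and on 10 at 12 h. The dispersion was a set value and was not estimated from these libraries, so recovery in the real data may differ. Unchanged genes passed in 0.588%, 0.868% and 0% of cases. Of 1000 random lists of 15 genes, 5.10% at 3 h and 3.00% at 6 h had p under 0.05 in the direction test. Alternatives covered stricter fold and FDR thresholds, Bonferroni adjustment, filters on low counts, the replicate block, each library left out, neighbouring copies counted singly, 0.5 of the annotated genes as the number tested, and, added later, the edgeR refit and the calls without the start of chromosome 1. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for all other steps.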

Results

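RNA sequencing measured gene expression in embryos of germinating rice (Oryza sativa) seeds from a wild type line and from the csa mutant at 3 h, 6 h and 12 h after the start of imbibition, the uptake of water that begins germination. CSA (CARBON STARVED ANTHER) encodes an R2R3 MYB transcription factor known for its part in partitioning sugar to the anther, and the comparisons asked which embryo transcripts differ without its normal function at each time. Each of the 6 groups held 3 samples, 18 in total, with RNA taken from 5 seeds per extraction. The labels do not say whether the replicates came from separate plants or seed lots. The authors' p-values and those of the edgeR fits therefore measure the spread between these samples, which may be technical. The Fisher, binomial, Poisson and permutation tests below take genes as units and do not measure that spread. The third wild type sample at 12 h is wild type by its title and description, while its genotype field names the mutant, and it was kept with the wild type. It had 0 raw counts of LOC_Os01g05510, against 78, 117 and 88 in the csa libraries at 12 h. For LOC_Os01g05530 it had 0, against 50, 112 and 64. For these genes, chosen after their values were seen, it was like the other wild type libraries.

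The deposited tables hold raw counts for the genes that the authors called, and totals over all genes were not used here. The library scaling factors recovered from the tables lay between 0.919 and 1.10, so relative depth was close to even within each time. Scaled counts below are raw counts divided by these factors, log2 fold changes are csa over wild type from the mean scaled counts, and errors of log2 values are standard errors with n = 3 per group.

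The mutated gene itself was lower in csa embryos at 6 h. CSA (LOC_Os01g16810) averaged 125 ± 59.9 scaled counts in csa against 325 ± 17.9 in wild type (SD, n = 3), a log2 fold change of -1.38 ± 0.40. Its raw counts were 92, 81 and 201 in the csa libraries and 310, 305 and 380 in the wild type libraries, so all 3 mutant values lay below all 3 wild type values. CSA was not among the called genes at 3 h or 12 h, and its counts at those times were not analysed here. Of a panel of 31 genes of sugar, abscisic acid and gibberellin biology, 13 were called at 1 or more times: 6 at 3 h, 8 at 6 h and 1 at 12 h.

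At 3 h, the called panel genes were all higher in csa. NCED5 and NCED3, which encode 9-cis-epoxycarotenoid dioxygenases of abscisic acid synthesis, had log2 fold changes of 2.64 ± 0.25 and 2.49 ± 0.38. SDR4, a regulator of seed dormancy, stood at 2.36 ± 0.41 and the dehydrin gene RAB16A at 1.58 ± 0.26. The alpha-amylase genes AMY3E and AMY1C, whose products break down starch, had log2 fold changes of 2.61 ± 0.81 and 1.57 ± 0.47. The AMY3E value leaned on csa replicate 2, with raw counts of 1658, 4291 and 801 in the csa libraries. NCED5 averaged 264 ± 79.1 scaled counts in csa against 42.6 ± 1.66 in wild type, and SDR4 644 ± 314 against 125 ± 5.97 (SD, n = 3). In the authors' deposited table the false discovery rate was 1.52e-19 for NCED5, 2.17e-15 for SDR4 and 0.042 for AMY1C.

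**Figure D1:**
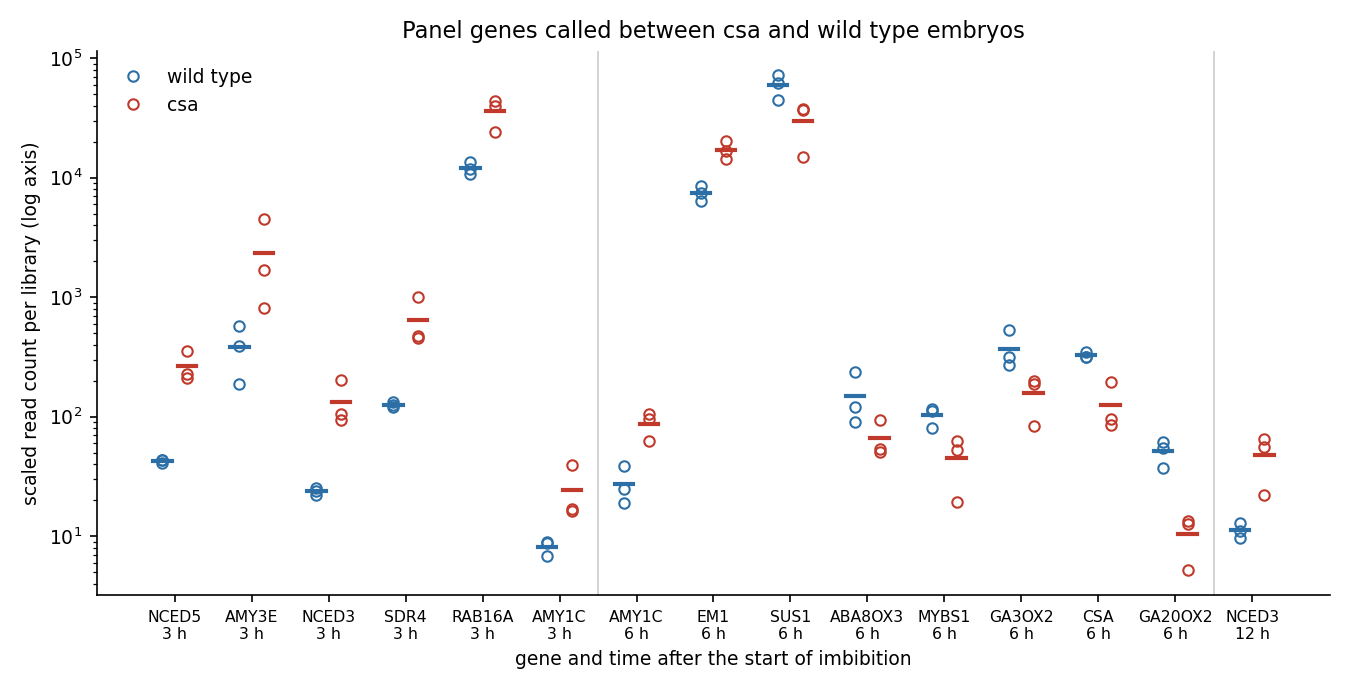
Scaled read counts of the called panel genes (log axis), with genes and times along the horizontal axis; circles are the 3 libraries of each genotype and bars their means. All 6 panel genes called at 3 h were higher in csa, and CSA at 6 h averaged 125 in csa and 325 in wild type.

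Across the genome, 1050 entries were called at 3 h, 746 of them higher and 304 lower in csa, so 71.0% were higher. Among the higher genes with the smallest p values, the desiccation-related protein gene LOC_Os05g05920 had a log2 fold change of 4.50 ± 0.34, the lipid transfer protein gene LOC_Os05g47730 3.51 ± 0.35, and the heat shock factor gene LOC_Os02g13800 2.64 ± 0.24. Genes lower in csa included a DNA polymerase delta-like gene (LOC_Os08g06620) at -4.01 ± 0.40, a 12-oxophytodienoic acid reductase gene (LOC_Os06g11290) at -1.59 ± 0.17, and the auxin-responsive SAUR genes LOC_Os04g56690 and LOC_Os08g35110 at -1.96 ± 0.21 and -1.31 ± 0.14.

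Among the annotation lists, all 16 called members of the seed storage and oil body list, which takes in lipid transfer proteins, were higher in csa at 3 h. They included a globulin 1 gene (LOC_Os03g46100) at 1.91 ± 0.38 and a lipid transfer protein gene (LOC_Os03g02050) at 1.48 ± 0.22. Of 15 late embryogenesis and dehydrin genes, which protect drying seed tissue, 14 were higher, among them RAB16D (LOC_Os11g26750) at 2.33 ± 0.31 and a group 1 gene (LOC_Os08g23870) at 2.26 ± 0.32. Of 22 defence genes, 21 were higher, with a class II chitinase gene (LOC_Os05g04690) at 4.66 ± 0.68. All 14 starch and sucrose entries and all 12 photosynthesis and plastid genes were higher as well, including a neutral invertase gene (LOC_Os01g22900) at 1.01 ± 0.17 and the photosystem II gene for PsbS (LOC_Os01g64960) at 2.40 ± 0.62. The starch and sucrose entries also held an alpha-amylase/trypsin inhibitor gene (LOC_Os03g45960), caught by the search terms. The 4 called endosperm marker genes, all glutelin or prolamin genes that also belong to the storage list, were higher too, and glutelin and prolamin transcripts are abundant in endosperm.

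Because most calls at 3 h were higher in csa, these counts were compared with the direction of all other calls. With Fisher's exact test (two-sided, Benjamini-Hochberg over 20 lists), none of the lists passed an adjusted p of 0.05. The smallest unadjusted p values from the same exact test, under 0.05, went to 4 lists: storage (Fisher's exact p = 0.00506, adjusted 0.0784), defence (p = 0.00784, adjusted 0.0784), starch and sucrose (p = 0.0142, adjusted 0.0943) and photosynthesis (p = 0.0233, adjusted 0.117). Late embryogenesis genes had an adjusted p of 0.324 and auxin genes, with 3 higher and 4 lower, 0.374. The other 14 lists each had an adjusted p of 1, heat shock among them with 13 higher and 4 lower. Csa replicate 2 stood farthest from its group at 3 h, with a median absolute log2 distance of 0.545 from the other csa libraries against 0.249 to 0.451 for the other libraries. Without it 653 calls were kept in an edgeR refit of the listed genes, without wild type replicate 3 there were 684, and no list passed in either case.

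Alpha-amylase isozyme 3A (LOC_Os09g28400) filled 2 entries of the 3 h table with different counts. The log2 fold change was 4.41 ± 0.70 in the entry with raw counts of 532, 293 and 103 in csa and 11, 11 and 24 in wild type. The gene identifiers beside these entries name AMY3D in RefSeq for that entry and AMY3A for the other, so which gene the counts belong to stayed open. Amylase, dehydrin and small heat shock genes occur as close copies, and how reads shared between copies were counted is not given in the sources used here.

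At 6 h, 2388 genes were called, 1395 higher and 993 lower in csa, so 58.4% were higher. The late embryogenesis and heat shock lists leaned to higher in csa, while the lists of nitrogen and amino acid genes and of cell wall genes leaned to lower. The higher side included a ZPT2-14-like zinc finger gene (LOC_Os03g60560, 2.34 ± 0.15), a group 1 late embryogenesis gene (LOC_Os06g21910, 1.91 ± 0.10), DREB1C (LOC_Os06g03670, 3.39 ± 0.43), which encodes a dehydration-responsive element-binding factor, and a raffinose synthase family gene (LOC_Os01g07530, 2.77 ± 0.37). On the lower side stood an alpha-xylosidase gene (LOC_Os01g03950, -2.05 ± 0.20), a peptide transporter gene (LOC_Os01g67630, -2.67 ± 0.34), an arabinofuranosidase gene (LOC_Os04g54810, -2.36 ± 0.29) and a peroxidase gene (LOC_Os04g56180, -2.15 ± 0.26). The raffinose synthase and alpha-xylosidase genes lie at the start of chromosome 1, a stretch described below.

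Heat shock and chaperone genes had 35 members higher and 1 lower in csa at 6 h. The heat shock factor gene LOC_Os02g32590, HSFA3 in RefSeq, averaged 4779 ± 238 scaled counts in csa against 930 ± 492 in wild type (SD, n = 3), a log2 fold change of 2.36 ± 0.44. A mitochondrial small heat shock protein gene (LOC_Os06g11610) stood at 1.38 ± 0.12 and a calmodulin-binding heat shock protein gene (LOC_Os07g29794) at 1.74 ± 0.27. Fisher's exact test against all other calls gave an adjusted p of 2.74e-06 (Benjamini-Hochberg over 22 lists). The list holds 4 neighbouring small heat shock genes from the start of chromosome 1, and without that stretch 31 members were higher and 1 lower, with an adjusted p of 3.24e-05 by the same test.

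All 15 called late embryogenesis and dehydrin genes were higher in csa at 6 h (Fisher's exact test, adjusted p = 0.00253). A dehydrin gene (LOC_Os01g12580) averaged 5103 ± 464 scaled counts in csa against 1038 ± 366 in wild type (SD, n = 3), and its log2 fold change was 2.30 ± 0.30. The desiccation-related gene LOC_Os05g05920 stood at 5.40 ± 0.76, the DHN1-like gene LOC_Os11g26570 at 1.54 ± 0.16, and EM1, an early-methionine type embryo protein gene of the panel that the list's search terms missed, at 1.18 ± 0.19.

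The lists of nitrogen and amino acid genes and of cell wall genes leaned the other way at 6 h. Of 38 genes with nitrogen, amino acid or peptide transporter annotation, enzymes included, 28 were lower and 10 higher in csa (Fisher's exact test, adjusted p = 8.86e-04). A cationic amino acid transporter gene (LOC_Os01g11160) had a log2 fold change of -2.41 ± 0.26 and the oligopeptide transporter gene YSL12 (LOC_Os04g44320) -1.58 ± 0.23, while an amino acid transporter-like gene (LOC_Os02g09810) stood at 1.42 ± 0.16. Of 37 cell wall genes, 26 were lower and 11 higher (adjusted p = 0.00313 by the same test). The beta-expansin gene EXPB4 (LOC_Os10g40730), whose product loosens the wall, stood at -2.28 ± 0.32, a pectate lyase gene (LOC_Os10g31910) at -2.56 ± 0.27 and a xyloglucan endotransglycosylase gene (LOC_Os11g33270) at -1.57 ± 0.18. A xylanase inhibitor gene (LOC_Os06g25010) of the same list was higher at 2.71 ± 0.43.

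The gibberellin synthesis genes GA20OX2 and GA3OX2 of the panel were lower in csa at 6 h, at -2.30 ± 0.42 and -1.24 ± 0.46, while GA20OX1 was not called. GA3OX2 lies at the start of chromosome 1 as well. The gibberellin list, whose search terms missed both genes, had 2 members higher and 1 lower at 6 h, too few to test. ABA8OX3, which encodes an abscisic acid 8'-hydroxylase that degrades the hormone, stood at -1.16 ± 0.53. Its raw counts were 52, 90 and 53 in the csa libraries and 89, 115 and 261 in the wild type libraries. The genotypes therefore overlapped, and the value leaned on wild type replicate 3. The MYB gene MYBS1 stood at -1.20 ± 0.45, and the sucrose synthase gene SUS1 averaged 0.499 times its wild type level. AMY1C was higher at 1.67 ± 0.37. The edgeR refit of the listed genes did not keep SUS1, whose fold change lay at the threshold.

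The other 18 lists tested at 6 h did not pass. Storage and oil body genes had 13 higher and 2 lower members (adjusted p = 0.143 by Fisher's exact test), MYB genes 5 higher and 11 lower (0.143), and auxin and glycolysis genes 6 and 4 higher against 11 and 8 lower (0.237 each). The remaining 14 had adjusted p values of 0.501 or more, among them starch and sucrose genes with 9 higher and 10 lower. The cell cycle, histone and replication list also fell in this group, with 32 higher and 17 lower (adjusted p = 0.644 by Fisher's exact test). So did the ribosome and translation list, with 8 higher and 4 lower (0.893). Their search terms also caught F-box genes with a cyclin-like domain and a rubber elongation factor gene, so these counts do not describe growth. The 2 called endosperm marker genes, both glutelin genes of the storage list, were higher. Csa replicate 3 stood farthest from its group at 6 h, with a median absolute log2 distance of 0.495 from the other csa libraries against 0.310 to 0.412 for the other libraries, and its CSA count was the highest of the mutant libraries. Without it the 4 lists above still passed, the largest adjusted p being 0.0147, whereas among genes with an absolute log2 fold change of 2 or more none passed.

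**Figure D2:**
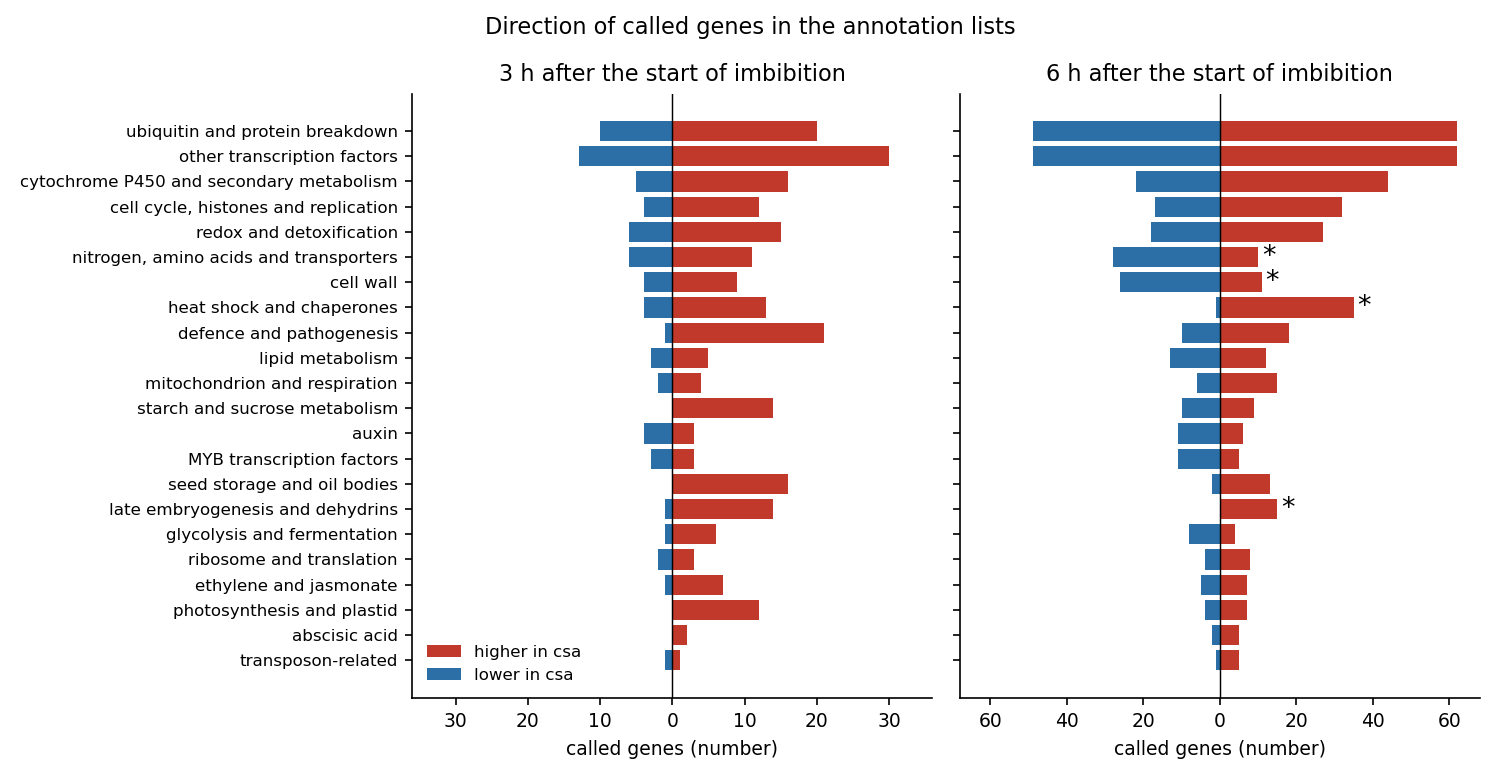
Numbers of called genes higher (red, right) and lower (blue, left) in csa in each annotation list at 3 h and 6 h, for lists tested at either time; stars mark an adjusted p under 0.05. No list is starred at 3 h and 4 are at 6 h, heat shock with 35 higher and 1 lower being the most one-sided of the larger lists. Late embryogenesis genes were 14 of 15 higher at 3 h and 15 of 15 at 6 h. Of all calls, 71.0% were higher at 3 h and 58.4% at 6 h. The lists were not tested between times.

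At 12 h, 85 genes were called, 45 higher and 40 lower in csa. NCED3, called at 3 h but not at 6 h, was higher, with a log2 fold change of 2.08 ± 0.41. NCED5 and SDR4 were called at 3 h only, and NCED1, NCED2 and NCED4 at no time. A glutelin gene (LOC_Os02g14600), the called endosperm marker at this time, stood at 2.17 ± 0.48, the small heat shock genes LOC_Os01g04350 and LOC_Os01g04360 at 2.21 ± 0.45 and 2.76 ± 0.52, and the group 1 late embryogenesis gene LOC_Os08g23870 at 1.61 ± 0.33. Lower genes included an aspartic peptidase family gene (LOC_Os01g04710) at -1.39 ± 0.14, a transferase family gene (LOC_Os01g01520) at -1.62 ± 0.26 and a Pto-like kinase gene (LOC_Os03g03280) at -1.65 ± 0.29. The cytosolic triosephosphate isomerase gene (LOC_Os01g05490), a step of glycolysis, was higher at 1.00 ± 0.15, although the edgeR refit did not keep it. This gene, the peptidase and transferase genes and both small heat shock genes lie at the start of chromosome 1, described below.

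No list had the 5 called members needed for a test at 12 h. The heat shock list had 3 members called, all higher, and redox genes 1 higher and 3 lower. The count at 12 h depended on the method: 39 of the 85 genes were kept in the edgeR refit, and leaving out single libraries left between 13 and 31, with 13 without csa replicate 2, the library farthest from its group at 0.564 against 0.316 to 0.453.

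Many genes were called at more than 1 time. In all, 3149 genes were called at any time and 2793 of them at a single time. At 3 h and 6 h, 327 were shared, of which 233 were higher and 49 lower at both times, so 86.2% kept their direction. Independent lists of these sizes among 21397 tested genes would share 48.6 genes higher at both times, 14.1 lower at both and 54.4 in opposite directions. The direction at 3 h went with the direction at 6 h (Fisher's exact test over the shared genes, two-sided, p = 5.25e-24). The 3 h and 12 h calls shared 29 genes, 25 with the same direction (Fisher's exact test, p = 1.49e-04), and the 6 h and 12 h calls shared 34, 31 with the same direction (Fisher's exact test, p = 1.44e-06). Without the start of chromosome 1, described below, these overlaps with 12 h held 17 and 21 genes. The 3 times have separate libraries, so these overlaps share no control samples.

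Of the genes called at all 3 times, 17 in number, 8 were higher and 8 lower throughout. At the start of chromosome 1, described below, lay 10 of the 17, among them 7 of the 8 lower genes. The lipid transfer protein gene LOC_Os05g47730 had log2 fold changes of 3.51 ± 0.35, 2.64 ± 0.51 and 1.46 ± 0.40 at 3 h, 6 h and 12 h, and the group 1 late embryogenesis gene LOC_Os08g23870 stood at 2.26 ± 0.32, 1.57 ± 0.24 and 1.61 ± 0.33. A conserved hypothetical gene (LOC_Os03g42235) stood at 5.53 ± 0.57, 5.37 ± 0.86 and 4.79 ± 0.41. A limonene cyclase-like gene of that stretch (LOC_Os01g01780) was lower throughout, at -2.91 ± 0.39, -3.15 ± 0.16 and -1.61 ± 0.46, although the edgeR refit did not keep its 12 h call. The lipid transfer protein gene LOC_Os08g03690 changed direction, at 1.18 ± 0.26, 2.15 ± 0.64 and -1.88 ± 0.56.

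Whether the csa effect itself differed between times was tested for the shared genes with an edgeR interaction term (quasi-likelihood test, Benjamini-Hochberg), added after the tables were seen and leaving out the alpha-amylase with 2 entries at 3 h. It differed between 3 h and 6 h for 57 of 326 genes at an adjusted p under 0.05, between 3 h and 12 h for 5 of 29 and between 6 h and 12 h for 3 of 34. Of these, 45, 4 and 3 were called in opposite directions, and such genes pass this test almost by construction. The other 12, 1 and 0 kept their direction. Genes called at a single time were not tested, so these shares do not show how often the csa effect changed with time. The peptide transporter gene LOC_Os01g67630 moved from 1.34 ± 0.38 at 3 h to -2.67 ± 0.34 at 6 h, and the small heat shock gene LOC_Os01g04350 from -1.69 ± 0.17 at 3 h to 2.21 ± 0.45 at 12 h.

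**Figure D3:**
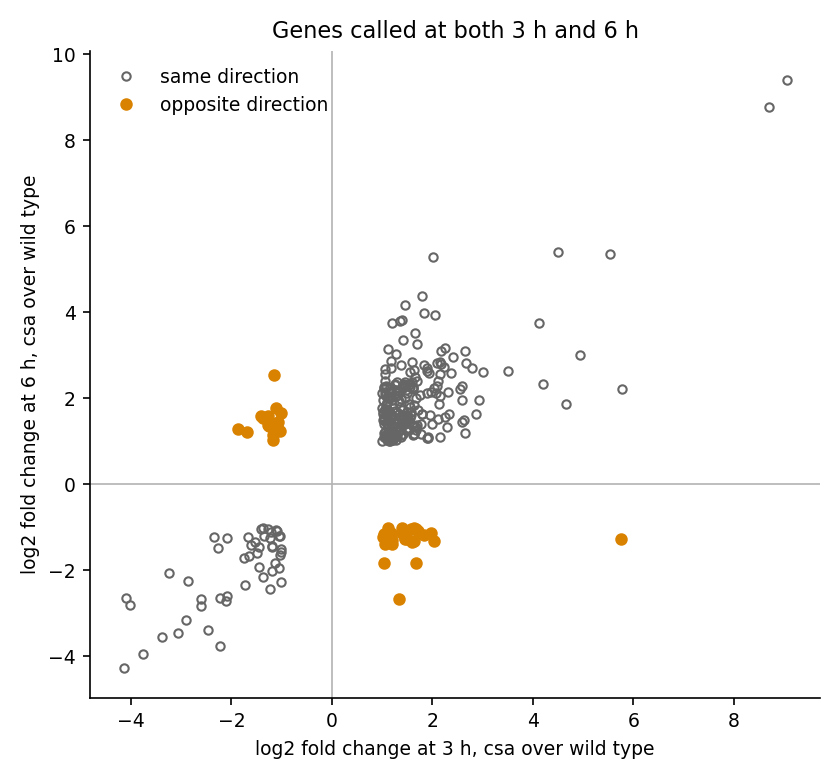
Log2 fold changes (csa over wild type, from the authors' deposited table) at 3 h (horizontal) and 6 h (vertical) of 326 genes called at both times; open circles share a direction and 45 filled circles do not. The points beyond 8 on both axes are 2 genes with 0 counts in wild type, whose fitted size has no fixed value.

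Called genes were crowded at the start of chromosome 1, a pattern examined only after it had been seen. Genes within its first 10000 identifier units made up 63 of 1050 calls (6.00%, exact binomial 95% interval 4.64 to 7.61) at 3 h, 103 of 2388 (4.31%, 3.53 to 5.21) at 6 h and 21 of 85 (24.7%, 16.0 to 35.3) at 12 h. The stretch spans 1.59% of the identifier range of the genome. At 12 h, 84.7% of the calls could be matched to RefSeq, and 16 of these 72 lay in the stretch, against 2.11% of RefSeq protein-coding genes (exact binomial test, p = 2.05e-12). CSA lies on the same chromosome outside the stretch. Over 130 windows of 5000 identifier units in the genome, the 2 windows of the stretch were the only ones past an adjusted p of 0.05 at 12 h (one-sided binomial test against an even spread, Benjamini-Hochberg). At 3 h and 6 h, 8 and 26 windows passed, on other chromosomes too. The test takes no account of gene density, so it cannot tell crowding in those windows from more genes. The windows of the stretch held 3.601 and 3.961 times the even number at 3 h, and 2.323 and 3.115 times at 6 h. By the same test their adjusted p values were 2.70e-07, 8.66e-09, 2.33e-05 and 1.35e-11. A chromosome 3 window stood at 2.376 times at 6 h (adjusted p = 1.43e-05). At 3 h and 6 h fewer than 80% of calls matched, so the shares of matched calls there, 5.81% and 4.42%, were not used as a test.

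Within the stretch, LOC_Os01g05510, a conserved hypothetical gene, had 0 counts in all wild type libraries at all 3 times. It averaged 74.8 ± 16.5, 78.5 ± 17.6 and 94.7 ± 11.5 scaled counts in csa at 3 h, 6 h and 12 h (SD, n = 3), at least 74.8-fold, 78.5-fold and 94.7-fold higher against a floor of 3 counts over the group. A Brix domain gene nearby (LOC_Os01g05530) had 0 counts in wild type at 3 h and 6 h and was at least 95.2-fold and 122-fold higher in csa against the same floor. The stretch also held genes lower in csa, with 29 lower beside 34 higher at 3 h and 60 beside 43 at 6 h.

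**Figure D4:**
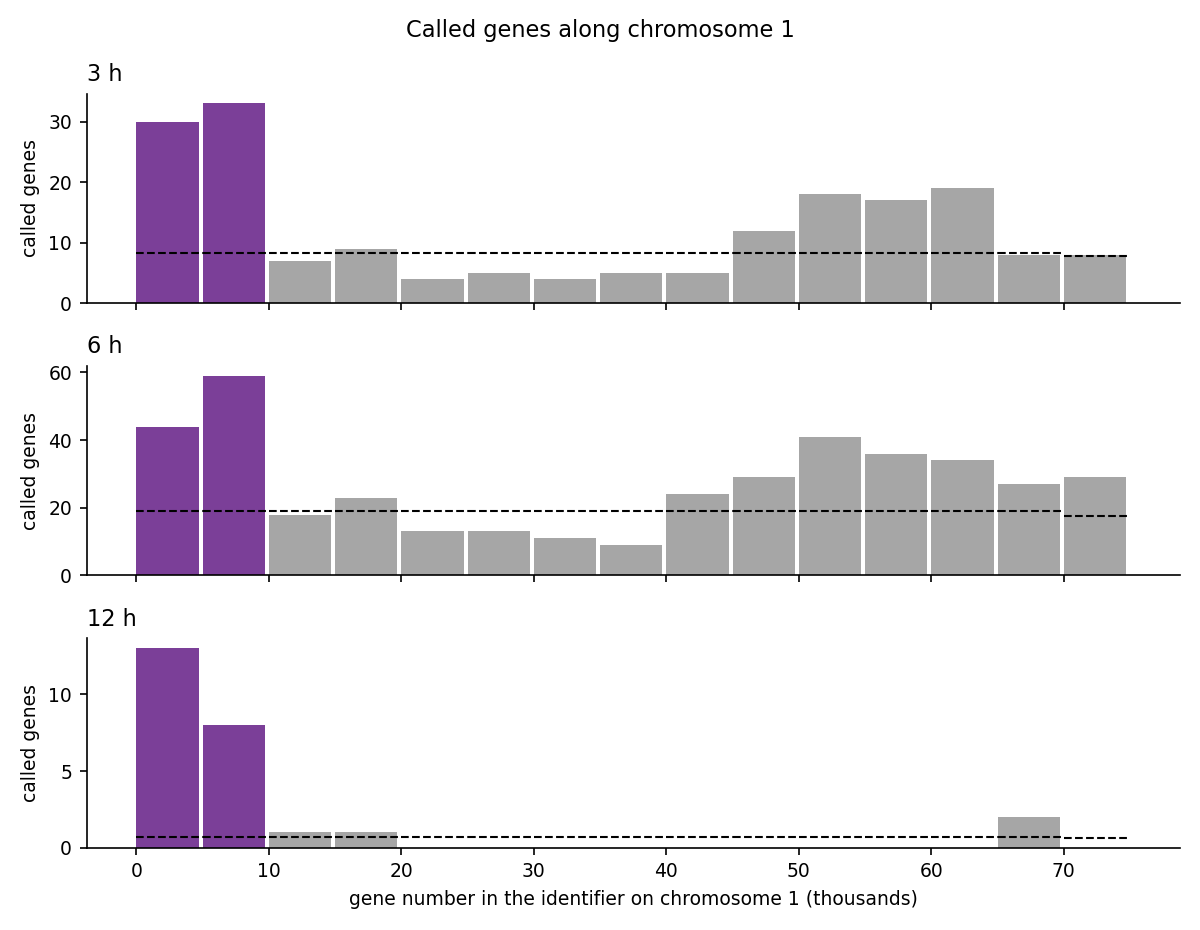
Called genes per window of 5000 identifier units along chromosome 1 at 3 h, 6 h and 12 h; dashed lines give the number under an even spread over the genome's identifier range, and purple bars are the start of the chromosome. The purple windows held 63, 103 and 21 calls, and at 12 h 21 of the 25 calls on the chromosome.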

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

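The interaction test and the count of false calls in this part were chosen after the results were seen.

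Between 3 h and 6 h, 45 genes were called in opposite directions in csa and all of them passed the edgeR interaction test of the difference. Of these, 28 were higher at 3 h and lower at 6 h, among them the peptide transporter gene LOC_Os01g67630, and 17 went the other way, among them a glucosyltransferase gene (LOC_Os01g45110) at -1.27 ± 0.24 and then 1.60 ± 0.43 (log2, SE, n = 3). Genes with opposite calls pass that test almost by construction, so a separate count was made of how many such genes false calls could give. With all false calls at the FDR threshold placed on the lists, 14.4 opposite genes would be expected, fewer than the 45 seen (exact Poisson test, p = 8.38e-11), but independent lists of these sizes would share 54.4, so 45 is no excess over chance overlap. What stays open is chance overlap of unrelated changes, a change of the csa effect with time or a shift in timing between the seed lots, which these data do not separate.

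Between 3 h and 12 h, 4 genes were called in opposite directions and passed the interaction test, the small heat shock gene LOC_Os01g04350 among them. Between 6 h and 12 h, 3 did so: the lipid transfer protein gene LOC_Os08g03690, a GRAB2-like gene (LOC_Os02g15340) and a thioredoxin fold gene (LOC_Os03g44650).

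The 6 libraries of each time can be split 10 ways into 3 against 3, too few for a share under 0.05. Only the real split, 1 of 10 at each time, gave as many genes past the refit's thresholds: 1002, 2276 and 39 genes at 3 h, 6 h and 12 h, against at most 4, 14 and 0 in the other splits. The listed genes were selected for the real split, so these counts decide nothing about chance.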

How the results depend on the processing

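The edgeR refit, the calls without the start of chromosome 1, the list tests with libraries left out, and the edgeR interaction and z test between times were chosen after seeing the data; all other settings were fixed before. In every setting genes could drop out but not change direction, so a list or overlap could turn only by losing genes. No list or overlap that passed turned significantly the other way, which is therefore little evidence of stability. The near-even 12 h balance (45 higher, 40 lower) tipped to lower under 4 settings: 17 and 19 with the replicate block, 19 and 20 in the edgeR refit, 15 and 16 without csa replicate 1, and 9 and 11 without wild type replicate 2. It moved most the other way, to 11 higher and 2 lower, without csa replicate 2. Among the settings of the main counts, 49 left a value within 1.5 times the reported one and 33 did not. At an absolute log2 fold change of at least 2, 188, 476 and 21 genes remained at 3 h, 6 h and 12 h, the shared genes fell to 49 (3 h and 6 h), 5 (3 h and 12 h) and 5 (6 h and 12 h), and 0 lists passed at 6 h: heat shock had 10 higher and 0 lower (adjusted p 0.16), late embryogenesis 5 and 0 (0.456), cell wall 3 and 7 (0.213), and nitrogen and amino acid genes 6 and 4 (1), so the lean of the nitrogen list to lower was lost among the larger changes. At an FDR of at most 0.001, 551, 1351 and 21 genes passed, and at 0.01, 44 at 12 h, 18 shared between 6 h and 12 h and 1 that differed between those times. Genes at or above the median count of their list numbered 525, 1194 and 43, and among them storage genes passed as the 1 list at 3 h and auxin joined the 4 lists at 6 h. Bonferroni adjustment left 413, 880 and 25. Replicate numbers did not pair the libraries (same-number correlations -0.05, 0.22 and 0.24 at 3 h, -0.21, 0.29 and 0.18 at 6 h, 0.01, 0.08 and 0.04 at 12 h; 8 of 18 libraries correlated best with their own number), and the replicate block gave 1007, 2314 and 36 genes. The edgeR refit of the listed genes kept 1002, 2276 and 39. Leaving out each library kept 653 to 921 genes at 3 h (653 without csa replicate 2, 684 without wild type replicate 3), 1575 to 1959 at 6 h (1575 without wild type replicate 2) and 13 to 31 at 12 h (13 without csa replicate 2, 31 without csa replicate 1, and 20 to 28 without each of the others), where fewer samples alone lower the count; 4 or 5 lists passed at 6 h, with MYB genes added without csa replicate 2 or wild type replicate 1, and 0 at 3 h. Without the start of chromosome 1 the shared genes were 17 (3 h and 12 h) and 21 (6 h and 12 h). With N set to 0.5 of the annotated genes, chance overlaps were 171, 6.1 and 13.9, against 117, 4.2 and 9.6. A test of all genes with DESeq2 and other pseudocounts were not run, since the tables hold called genes and raw counts. Apart from changes that fewer samples or genes bring, the cause was not tested. With 3 samples per group, genes changed by a log2 fold near 1 are the least secure. By p and direction alone, 79%, 87% and 30% of such simulated changes were recovered at 3 h, 6 h and 12 h. The p limits there were 0.00694, 0.0117 and 0.000255. A real gene also needed an absolute log2 fold change of at least 1 to be kept. Recovery under that full rule was not measured and can only be lower.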

Other observations

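Tests of gene density, of kept direction and of reads that map differently in the chromosome 1 stretch, and of the wild type course of list members, were chosen after the result was seen.

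Genes of the hormone lists, which did not pass, were also called at 6 h. The protein phosphatase 2C genes LOC_Os06g48300 and LOC_Os03g55320 had log2 fold changes of 1.60 ± 0.21 and 1.45 ± 0.22 (SE, n = 3), while a gene for an abscisic acid responsive element-binding factor (LOC_Os06g10880) stood at -1.39 ± 0.11. Auxin response factor 1 (LOC_Os04g56850) and the auxin-conjugating enzyme gene GH3.4 (LOC_Os05g42150) were lower, at -2.04 ± 0.27 and -1.46 ± 0.13, and a dormancy and auxin associated gene (LOC_Os09g26620) was higher at 1.97 ± 0.35. An ethylene receptor gene (LOC_Os07g15540) stood at 1.48 ± 0.21. The abscisic acid list had 5 higher and 2 lower members at 6 h and the auxin list 6 and 11, and neither passed the direction test, though auxin passed among genes at or above the median count.

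Some single genes of lipid use and redox protection were also called, although neither list departed from the other calls: lipid metabolism genes had 5 higher and 3 lower at 3 h (Fisher's exact test, adjusted p = 1) and 12 and 13 at 6 h (0.624), and redox genes had adjusted p values of 1 and 0.968. At 3 h the isocitrate lyase gene (LOC_Os07g34520), a step by which germinating seeds turn oil into sugar, stood at 1.54 ± 0.31 and catalase A (LOC_Os02g02400) at 1.37 ± 0.15. At 6 h a 1-Cys peroxiredoxin gene (LOC_Os07g44440), of a type typical of seed embryos and aleurone, stood at 2.86 ± 0.47, a catalase isozyme 2 gene (LOC_Os03g03910) at 1.89 ± 0.33 and the 18 kDa oleosin gene (LOC_Os03g49190) at 1.11 ± 0.13. A fructokinase gene (LOC_Os08g02120) was lower at -1.63 ± 0.40. Of 45 redox genes called at 6 h, 27 were higher and 18 lower.

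A first hypothesis concerns the crowding of calls at the start of chromosome 1. Gene density alone is argued against as the source, since the stretch held 22.2% of matched 12 h calls against 2.11% of annotated genes. For a difference in germination stage, 63.5% of 3 h calls in the stretch (40 of 63) recurred at 6 h in the same direction against 24.5% outside it (Fisher's exact test, p = 3.38e-10). The stretch was picked for its dense calls, and denser calls at each time raise recurrence there by themselves. This contrast therefore cannot decide on a difference in germination stage. A segment that differs in sequence between the lines stays open: of genes called at both 3 h and 6 h, 97.6% in the stretch (40 of 41) kept their direction against 84.6% outside it, a contrast (Fisher's exact test, p = 0.0262) too weak to decide in a test chosen afterwards. Whether expression or only read mapping differs cannot be told apart without alignments, as the 2 genes of the stretch with 0 wild type counts fit both.

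A second hypothesis concerns the 4 lists that passed at 6 h, late embryogenesis and heat shock genes leaning to higher and nitrogen and amino acid genes and cell wall genes to lower. Without csa replicate 3 the edgeR refit kept 33 higher and 1 lower heat shock members and 13 and 0 late embryogenesis members. It kept 8 and 21 cell wall members and 8 and 18 nitrogen and amino acid members. Csa replicate 3 as the sole source is argued against for these members, which passed the p and fold limits without it. The genes were called with that library and could not change direction, so the lean of the 4 lists without it is no separate evidence. If csa embryos were less far along the wild type course, members higher in csa should decline in wild type: from 3 h to 6 h the median wild type change was -1.55 log2 units for 21 higher members and 1.41 for 6 lower members, a difference of -2.96 (95% bootstrap interval -4.05 to -1.86, permutation p = 2.80e-04), but only 27 of the 126 members were called in 1 direction at both times, so a slower course stays open, as does a difference in age or storage of the seed lots, which was not tested. Over all genes called in 1 direction at both times, less 2 with 0 wild type counts, the difference between 231 higher and 49 lower genes was -1.41 (-1.84 to -1.15, permutation p = 1e-05, the smallest 100000 permutations can give), -1.82 (-2.40 to -1.37) without the start of chromosome 1, and -1.11 (-1.47 to -0.77) within csa. The genes were sorted by calls from these same libraries, so the permutation p values do not test the course apart from that selection. Endosperm left on csa embryos cannot be told apart from a higher level in the embryo, since 2 endosperm marker genes were called at 6 h, both higher, and their uncalled partners were not analysed here.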
